A study of Homo sapiens and Mus musculus with 30 samples.

How the data were processed

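RNA was measured by sequencing in 30 samples. Of these, 18 were libraries of the cell lines AGS, NUGC3 and Hs746T after siRNA. The other 12 were entries for NUGC3 subcutaneous tumours, 6 listed for human and 6 for mouse genes. The deposited values were TPM, expression scaled by the authors to transcript length and to a common total within each library, in 5 tables of 6 libraries. The unit comes from the names of the tables and from the control libraries, whose values add up to that total within rounding. Per the labels, directional libraries of total RNA were made and sequenced by a service provider. The aligner, the quantification tool, the genome build, the annotation and the way human and mouse reads were parted are not given in the sources used here, so no coordinates are given. TPM keeps no depth, so no counting intervals could be computed. The tables were normalised separately, and levels were not compared between them, except as mouse to human TPM ratios in the test of reads shared between species.

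Some properties of the tables were checked on the values. They listed 16058, 19334, 17739, 16797 and 13604 genes for AGS, NUGC3, Hs746T and the human and mouse genes of tumours. In each, 0 genes had 0 in all 3 control libraries, while 531, 402, 664, 723 and 266 had 0 in all 3 knockdown libraries. Knockdown libraries fell short of the full TPM total by 16.8 to 21.6 TPM in AGS, 20.4 to 30.4 in NUGC3, 10.8 to 30.9 in Hs746T, 78.0 to 102 in the human genes and 454 to 473 in the mouse genes of tumours. A gene expressed only after knockdown is therefore absent from the tables, which biases the counts against rises. The mouse table held 21 genes whose names had been turned into dates by a spreadsheet. They took at most 0.164% of a library's TPM and were left out. No 2 libraries of a table were identical (0 pairs in each table).

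Each comparison used its own 6 libraries, 3 control and 3 knockdown, grouped by the labels. Genes with at least 1 TPM in at least 3 of the 6 were tested on log2(TPM + 1) with limma 3.58.1 and statmod 1.5.0 in R 4.3.3 (lmFit, then eBayes with trend and robust set). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Errors beside means are SDs and errors beside log2 changes are SEs from the fit. Gene lists, 16 human and 19 mouse, were tested with limma's camera at a correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A list needed at least 3 tested members, which 1 mouse list, for skin epithelium, did not have (1 tested member). Differences between cell lines were tested in a fit of all 18 siRNA libraries, as contrasts of the effects. These comparisons, tests, lists and filters were fixed before the data were examined.

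Named genes followed a rule: IQGAP1, IQGAP2 and IQGAP3, the 5 largest rises and 5 largest falls among called genes whose 3 values in one arm all lay outside the range of the other arm (chance gives 10% of genes such a split), the 2 called members with the largest change from each of the 6 lists with the smallest camera p, and up to 10 genes called alike in all 3 lines. Other list members, and AKR1C3 and OLFM4 in cultured cells, were chosen after their values were seen. Some genes that the rule picks are not named.

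Replicate numbers were checked as pairs by correlating, across genes, the deviations of equally numbered control and knockdown libraries from their group means. They paired in AGS (0.274 to 0.37), NUGC3 (0.302 to 0.551) and Hs746T (0.711 to 0.877), but in NUGC3 libraries of unlike number reached 0.362, above 2 of its 3 pairs, against at most 0.0025 in AGS and 0.458 in Hs746T. The fit was repeated with the replicate number as a block, and its value is given where it changes a call or moves a count by more than 1.5 times.

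The limma fit was tested on simulated data with the spread of each comparison. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 73.1%, 97.0% and 100% in AGS, 64.2%, 83.6% and 95.5% in NUGC3, 11.9%, 50.7% and 87.9% in Hs746T, 5.97%, 34.3% and 78.8% in the human genes of tumours, and 1.49%, 8.96% and 57.6% in the mouse genes. It called 13, 5, 3, 4 and 3 of the unchanged genes.

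Words of 7 bases in 3' UTRs were taken from the GENCODE basic annotation, version 29, matched by gene symbol, for genes with a 3' UTR of at least 50 bases. These were 11021 of 11312 tested genes in AGS, 11780 of 12145 in NUGC3, 12137 of 12492 in Hs746T and 12006 of 12308 in tumours. A 3' UTR of any length was found for 97.8% to 98.3% of the tested human genes. The longest one of each symbol was searched, which need not be the form that the cells made. Each word's presence was regressed on the rank-normalised log2 change, with UTR length and GC content and their squares as covariates, and called past a Bonferroni threshold over 16384 words (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). Differences between genes with and without a word come from the same regression on the log2 change itself. Alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 TPM, median centring, quantile normalisation, eBayes without trend and robust, the replicate block, a joint fit of the siRNA libraries, an estimated correlation in camera, and each library left out in turn. A table filter mirrored onto the knockdown libraries, and Hs746T without both libraries numbered 1, were added after the data had been seen.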

Results

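RNA sequencing compared IQGAP3 knockdown with control in 3 human gastric cancer cell lines, AGS, NUGC3 and Hs746T, and in subcutaneous tumours grown from NUGC3 cells. IQGAP3 is a member of the IQGAP family of scaffold proteins, which bind small GTPases and the actin cytoskeleton. The cultured lines received pools of siRNAs at 35 nM, directed against IQGAP3 (siIQGAP3) or non-targeting (siCtrl), 24 hours after seeding and again 72 hours later, and were harvested 48 hours after the second transfection. The tumours came from NUGC3 cells that stably carried an shRNA, labelled shIQGAP3 or shCtrl. Their human genes, from the cancer cells, and their mouse genes, from the host's stromal cells, were listed as separate samples. Whether both came from the same tumours is not given in the sources used here, so the human and mouse comparisons may not be independent. Each of the 10 groups held 3 libraries, which gave 30 samples and 6 libraries in each of 5 comparisons. Expression was given as TPM, a unit scaled to the length of each transcript and the total of each library that keeps no record of sequencing depth, so the depth is unknown. Between 9852 and 12682 genes reached 1 TPM in a library. The labels do not say that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Changes are differences in log2(TPM + 1), which understate the change of low genes, and each adjusted p is from limma with Benjamini-Hochberg adjustment.

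IQGAP3 itself was lower in every siIQGAP3 library than in every siCtrl library of the same line. In AGS it stood at 79.3, 88.8 and 93.3 TPM in the control libraries and 15.5, 13.6 and 18.1 TPM after knockdown, 18.0% of the control mean (log2 change -2.40 ± 0.10, SE, n = 3 per group, adjusted p = 2.62e-09). In Hs746T it went from 37.7, 29.9 and 34.1 TPM to 8.26, 6.03 and 6.58 TPM, or 20.5% (log2 change -2.14 ± 0.16, adjusted p = 0.00293). In NUGC3 cells the control libraries were uneven, at 116, 40.5 and 32.5 TPM, against 14.9, 15.6 and 8.52 TPM after knockdown, or 20.6% (log2 change -2.01 ± 0.49, adjusted p = 0.0172). That call was lost with the replicate number as a block (adjusted p = 0.0782) and without any single siIQGAP3 library (adjusted p = 0.0744 without replicate 1, 0.0817 without replicate 2 and 0.0840 without replicate 3). IQGAP3 was not called lower in the tumours. Its human transcript stood at 27.6, 20.9 and 27.5 TPM in shCtrl tumours and 22.8, 15.0 and 21.0 TPM in the libraries labelled shIQGAP3, or 77.3% (log2 change -0.37 ± 0.21, adjusted p = 0.396). Mouse Iqgap3, in host cells that carried no shRNA, fell to 19.9% of control, from 12.2, 7.14 and 12.4 TPM to 2.74, 0.81 and 2.76 TPM (log2 change -1.94 ± 0.41, adjusted p = 0.0216). It lost the call without shCtrl replicate 1 (adjusted p = 0.0808), shCtrl replicate 3 (0.0884) or shIQGAP3 replicate 3 (0.0501).

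**Figure D1:**
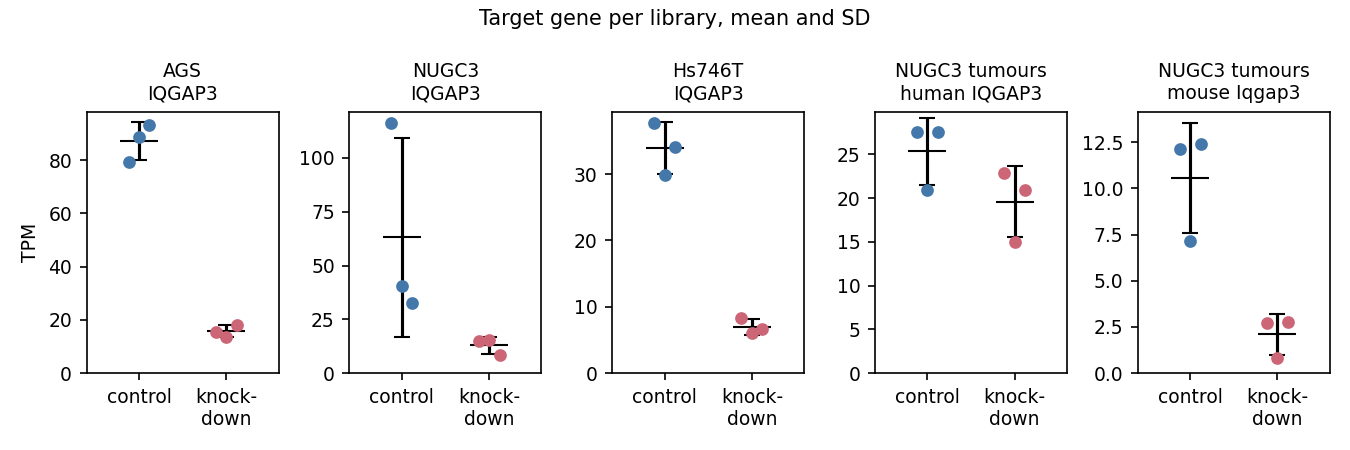
IQGAP3 (human) or Iqgap3 (mouse) expression in TPM for each of the 6 libraries of the 5 comparisons, with points for libraries, a dash for the group mean and bars for 1 SD (n = 3). Knockdown libraries lie at 18.0% to 20.6% of the control mean in the cultured lines and at 77.3% for human IQGAP3 in tumours.

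The related genes moved in some samples. IQGAP1, a widely expressed relative of IQGAP3, fell from 197 ± 18.7 to 135 ± 3.92 TPM (mean ± SD, n = 3) in NUGC3 cells (log2 change -0.54 ± 0.08, adjusted p = 0.00064). It was not called in AGS (0.11 ± 0.07, adjusted p = 0.226), in Hs746T (0.20 ± 0.14, adjusted p = 0.461, or 0.0239 with the replicate block) or in tumours (-0.34 ± 0.39, adjusted p = 0.691). IQGAP2, reported as a tumour suppressor in several cancers, fell in the human genes of tumours labelled shIQGAP3, from 14.2 ± 1.85 to 3.50 ± 1.75 TPM (log2 change -1.82 ± 0.28, adjusted p = 0.0051). It was not called in AGS (-0.10 ± 0.09, adjusted p = 0.414) and was too low to test in NUGC3 and Hs746T cells. Mouse Iqgap1 (-0.51 ± 0.55, adjusted p = 0.571) and Iqgap2 (0.52 ± 0.37, adjusted p = 0.393) were not called.

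In AGS cells, knockdown came with more mRNA from interferon-stimulated genes and cholesterol synthesis genes and less from genes of ribosome biogenesis. Of 25 interferon response genes, 20 rose, 0 fell and 5 were not called. CXCL10, a chemokine that attracts T cells, rose from 4.65 ± 0.863 to 14.7 ± 2.68 TPM (log2 change 1.48 ± 0.14, adjusted p = 5.01e-06). IFIT1, which binds viral RNA, rose from 23.2 ± 1.28 to 59.5 ± 5.06 TPM (log2 change 1.32 ± 0.08, adjusted p = 7.65e-08). ISG15, a ubiquitin-like protein induced by interferon, rose by 1.12 on the same scale. The list lay above other genes in camera (adjusted p = 4.56e-08), but not with an estimated correlation between genes (adjusted p = 0.209 with an estimated correlation). Adjusted over the list alone, 20 genes rose and 1 fell.

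Ribosome biogenesis genes went the other way in AGS, where 0 of 20 rose, 11 fell and 9 were not called, the same counts when adjusted over the list alone. NOP16 and NOP2, nucleolar proteins needed to build the large ribosomal subunit, fell by 0.56 ± 0.07 and 0.53 ± 0.07 (adjusted p = 1.98e-05 and 7.36e-05). The list's camera test gave an adjusted p = 0.000132, and an adjusted p = 0.666 with an estimated correlation. Among 20 cholesterol synthesis genes, 10 rose, 0 fell and 10 were not called, or 12 higher adjusted over the list alone. CYP51A1, the lanosterol demethylase, rose from 54.1 ± 7.36 to 88.3 ± 21.5 TPM (adjusted p = 0.0276), and MVD, of the mevalonate pathway, from 49.6 ± 5.93 to 80.4 ± 16.5 TPM (adjusted p = 0.0141). This list passed camera (adjusted p = 0.000378), with an adjusted p = 0.878 with an estimated correlation. Of the markers of other cell types, all 4 that could be tested fell, also when adjusted over the list alone. They were CD68, a lysosomal protein of macrophages (log2 change -1.63 ± 0.12, adjusted p = 2.18e-07), the myelin gene MBP (-0.86 ± 0.10, adjusted p = 1.98e-05), the muscle filament gene DES (-0.82, adjusted p = 0.00548) and the growth factor receptor PDGFRA (-0.41, adjusted p = 0.0386). Camera gave an adjusted p = 0.0027 for them, and an adjusted p = 0.425 with an estimated correlation.

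The largest rises in AGS were in FGG, the fibrinogen gamma chain (log2 change 2.78 ± 0.30, adjusted p = 0.00112), NPPB, a natriuretic peptide (2.78 ± 0.56, adjusted p = 0.0203), and UBD, a ubiquitin-like protein induced by inflammatory cytokines (2.69 ± 0.19, adjusted p = 1.44e-06). CCL4L2 (2.71 ± 0.46, adjusted p = 0.0101) and CCL4L1 (2.66 ± 0.29, adjusted p = 0.000835) also rose, but these chemokine genes are near-identical copies and the split between them is uncertain. The largest falls were in APOA2, an apolipoprotein of HDL, from 57.7 ± 21.2 to 1.48 ± 0.475 TPM (log2 change -4.51 ± 0.34, adjusted p = 0.000375), and IGFL1, an insulin growth factor-like gene, from 16.8 ± 3.09 to 0.393 ± 0.0802 TPM (-3.66 ± 0.13, adjusted p = 1.12e-09). PSG5 (-3.09 ± 0.45, adjusted p = 0.00561), which shares sequence with other pregnancy-specific glycoprotein genes and is uncertain for that reason, MYO15B (-2.89 ± 0.11, adjusted p = 1.6e-09) and the serine protease inhibitor SERPINB2 (-2.88 ± 0.24, adjusted p = 0.00012) followed.

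Of 11312 genes tested in AGS, 2655 rose and 2001 fell, and 128 and 170 of these changed at least 2-fold. With median centring 2381 rose and 2362 fell, or 2484 and 2310 after quantile normalisation. 4 of 16 lists passed camera, and 0 did with an estimated correlation (limma camera, lowest adjusted p = 0.209, with 1 at an unadjusted p under 0.05). With the replicate block 6 lists passed, the added ones being ATF4 and ER stress (adjusted p = 0.0306, against 0.0521 without the block), where 9 of 18 genes rose and 1 fell, and inflammatory cytokines (adjusted p = 0.00821, against 0.0521), where 5 of 12 rose and 1 fell, both counts without the block. Both had an adjusted p = 0.778 with the block and an estimated correlation. Examples were the ER chaperone cofactor DNAJB9 (0.96 ± 0.17, adjusted p = 0.00128), the asparagine synthetase ASNS (0.91 ± 0.13, adjusted p = 0.000411), the neutrophil chemokine CXCL2 (1.44 ± 0.19, adjusted p = 0.000236) and TNFAIP3, an inhibitor of NF-kappaB signalling, which fell (-1.01 ± 0.21, adjusted p = 0.00667).

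In NUGC3 cells, knockdown came with more mRNA from DNA replication and mitosis genes and less from interferon response, ERK target and mesenchymal genes. Of 31 DNA replication genes, 18 rose, 0 fell and 13 were not called. RRM2, a subunit of the enzyme that makes deoxynucleotides, rose from 194 ± 3.26 to 696 ± 29.4 TPM (log2 change 1.84 ± 0.06, adjusted p = 3.83e-07). E2F1, a transcription factor of the G1/S transition, rose from 41.3 ± 2.3 to 122 ± 7.77 TPM (1.54 ± 0.08, adjusted p = 2.96e-06). The list passed camera with an adjusted p = 3.85e-07, and had an adjusted p = 0.359 with an estimated correlation. Of 30 mitosis genes, 15 rose, 2 fell and 13 were not called, among them BIRC5, an inhibitor of apoptosis in the chromosomal passenger complex (0.74 ± 0.07, adjusted p = 4.04e-05), and the spindle factor TPX2 (0.54 ± 0.07, adjusted p = 0.000308). Their camera test gave an adjusted p = 0.000691, and an adjusted p = 0.359 with an estimated correlation. Both lists had the same counts when adjusted over the list alone.

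Interferon response genes of NUGC3 cells fell: 17 of 21, against 1 that rose and 3 that were not called (18 lower and 1 higher adjusted over the list alone). IRF9, the DNA-binding part of the interferon-activated complex ISGF3, fell from 53.2 ± 14.9 to 12.0 ± 0.957 TPM (log2 change -2.02 ± 0.19, adjusted p = 4.63e-05), and its partner STAT2 fell by 1.19 (adjusted p = 9.11e-05). IFI44 fell by 1.88 ± 0.21 (adjusted p = 0.000126). The exception was BST2, a membrane protein that holds back budding viruses, which rose by 0.28 (adjusted p = 0.0209). Camera placed the list below other genes (adjusted p = 4.14e-05), but had an adjusted p = 0.421 with an estimated correlation. Of 23 genes that respond to the ERK pathway, 16 fell, 2 rose and 5 were not called, also when adjusted over the list alone. ETV1, a transcription factor, fell by 2.01 ± 0.12 (adjusted p = 4.34e-06), and AREG, a ligand of the EGF receptor, fell from 160 ± 22.7 to 58.1 ± 18.3 TPM (-1.48 ± 0.20, adjusted p = 0.000367). KCNN4, a potassium channel (0.47, adjusted p = 0.00424), and ETV5 (0.54, adjusted p = 0.00364) rose. The ERK list passed camera (adjusted p = 0.000691), with an adjusted p = 0.359 with an estimated correlation.

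Mesenchymal genes of NUGC3 cells also fell, 7 of 9, with 0 higher and 2 not called, also when adjusted over the list alone. VIM, the intermediate filament vimentin, fell from 7.09 ± 2.67 to 0.373 ± 0.396 TPM (log2 change -2.54 ± 0.26, adjusted p = 7.27e-05), and SNAI2, a repressor of epithelial genes, from 43.4 ± 8.56 to 8.37 ± 1.02 TPM (-2.23 ± 0.15, adjusted p = 7.63e-06). Fibronectin, FN1, fell by 1.71 (adjusted p = 5.47e-05). The list's camera test gave an adjusted p = 0.00303, and an adjusted p = 0.359 with an estimated correlation. Without siCtrl replicate 3 its adjusted p was 0.0796. Of 7 gastric differentiation and stem cell genes, 5 fell, 1 rose and 1 was not called, the same counts adjusted over the list alone. The trefoil peptides TFF1 and TFF2, which protect the gastric mucosa, fell by 1.95 ± 0.17 and 1.75 ± 0.24 (adjusted p = 2.74e-05 and 0.000352), and STMN1, which destabilises microtubules, rose by 0.46 (adjusted p = 0.00748). This last list passed camera with an adjusted p = 0.0379 and had an adjusted p = 0.359 with an estimated correlation. It was not past the threshold without siCtrl replicate 1 (adjusted p = 0.189), 2 (0.186) or 3 (0.351).

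The largest rises in NUGC3 cells were in HEG1, a receptor at endothelial cell junctions, from 2.36 ± 0.469 to 19.7 ± 1.48 TPM (log2 change 2.63 ± 0.14, adjusted p = 2.72e-06), the cytokine TNFSF18 (2.43 ± 0.23, adjusted p = 4.56e-05), the gap junction gene GJA5 (2.39 ± 0.31, adjusted p = 0.000319), VGLL1, a cofactor of TEAD transcription factors (2.37 ± 0.08, adjusted p = 3.83e-07), and the carboxypeptidase CPA4 (2.36 ± 0.26, adjusted p = 0.00011, or 0.0629 with the replicate block). The largest falls were in MMP1, the interstitial collagenase, from 241 ± 121 to 8.82 ± 3.95 TPM (-4.59 ± 0.40, adjusted p = 0.000176), and IL37, an anti-inflammatory cytokine, from 58.5 ± 11.9 to 1.67 ± 0.537 TPM (-4.48 ± 0.18, adjusted p = 8.38e-07). AKR1C1 (-3.93 ± 0.72, adjusted p = 0.00697) is close in sequence to other aldo-keto reductases and is uncertain. The stress keratin KRT16 (-3.75 ± 0.17, adjusted p = 1.2e-06) and the parathyroid hormone-like gene PTHLH (-3.51 ± 0.13, adjusted p = 3.83e-07) fell as well.

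Of 12145 genes tested in NUGC3 cells, 2057 rose and 3292 fell, 179 and 540 of them at least 2-fold. More genes fell than rose only with the values as they stood: the library medians differed by -0.104 between the groups on the log2 scale, and with that shift removed 2996 rose and 2581 fell, or 2931 and 2637 after quantile normalisation. 6 of 16 lists passed camera and 0 with an estimated correlation (limma camera, lowest adjusted p = 0.359, with 0 at an unadjusted p under 0.05). The block added the TGF-beta targets (adjusted p = 0.0323, against 0.196 without it, and adjusted p = 0.588 with the block and an estimated correlation), of which 12 of 23 fell and 6 rose without the block. Control library 1 held the high IQGAP3 value, and without it 1980 genes rose and 2448 fell, with 4215 of the calls kept. Without it 11 of 16 interferon response genes still tested fell and 0 rose, as did 4 of 7 mesenchymal genes.

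In Hs746T cells after knockdown, ERK targets, inflammatory cytokines, mesenchymal genes and interferon response genes lay lower as lists by camera, with few members called. Of 24 ERK targets, 3 fell, 0 rose and 21 were not called, or 13 lower and 1 higher adjusted over the list alone. AREG fell from 28.8 ± 6.94 to 10.8 ± 1.35 TPM (log2 change -1.32 ± 0.19, adjusted p = 0.0204), and DUSP5, a phosphatase that switches off ERK, fell by 1.00 ± 0.13 (adjusted p = 0.0136). With the replicate block 18 fell and 1 rose. The list passed camera with an adjusted p = 7.57e-08, and had an adjusted p = 0.201 with an estimated correlation. Of 18 inflammatory cytokine genes, 3 fell, 0 rose and 15 were not called, also when adjusted over the list alone (10 lower and 1 higher with the block). CXCL8, which attracts neutrophils, fell from 34.2 ± 7.76 to 10.2 ± 1.91 TPM (-1.65 ± 0.20, adjusted p = 0.0131), and IL1A fell by 1.20 ± 0.24 (adjusted p = 0.0474). The IL1A call was lost without any of 5 libraries (limma adjusted p = 0.066 to 0.216). Those of CXCL8, AREG and DUSP5 were each lost without any of 4 (up to 0.0774, 0.121 and 0.0908). Camera gave an adjusted p = 0.00248 for the cytokines, and an adjusted p = 0.201 with an estimated correlation.

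VIM led the mesenchymal genes of Hs746T, from 5939 ± 720 to 682 ± 78.8 TPM (log2 change -3.12 ± 0.14, adjusted p = 0.000467). The membrane-bound metalloproteinase MMP14 fell by 0.79 ± 0.14 (adjusted p = 0.0365), and the cadherin CDH2 rose by 0.72 (adjusted p = 0.0276). The other 14 of 17 were not called, and 4 fell and 1 rose adjusted over the list alone, or 11 and 4 with the block. The list passed camera (adjusted p = 0.00783), with an adjusted p = 0.61 with an estimated correlation. Of 24 interferon response genes, ISG20, an exonuclease that degrades viral RNA, fell (-0.87 ± 0.18, adjusted p = 0.046), 0 rose and 23 were not called, the same adjusted over the list alone. The ISG20 call was lost without any of 5 libraries (limma adjusted p = 0.0551 to 0.194). The list mean lay 0.85 below other genes (camera adjusted p = 1.95e-05, and adjusted p = 0.87 with an estimated correlation). With the block 21 fell, and without the libraries numbered 1 of both arms 16 fell. MBP (-0.82 ± 0.18, adjusted p = 0.057) and RRM2 (0.62 ± 0.13, adjusted p = 0.0516) were not called. The block called both (adjusted p = 3.91e-05 and 0.00037), and it added the markers of other cell types to the lists past camera (adjusted p = 0.0361, against 0.104, and adjusted p = 0.5 with the block and an estimated correlation).

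The largest rises in Hs746T were in CCNG1, cyclin G1 and a p53 target, from 15.7 ± 4.99 to 64.5 ± 11.4 TPM (log2 change 2.00 ± 0.25, adjusted p = 0.0136), POLDIP2, which binds DNA polymerase delta (1.78 ± 0.13, adjusted p = 0.00293), HEG1 (1.75 ± 0.11, adjusted p = 0.0021), the deacetylase SIRT2 (1.68 ± 0.23, adjusted p = 0.0159) and TMEM250 (1.66 ± 0.10, adjusted p = 0.00168). The largest falls, beside VIM, were in MMP1, from 1048 ± 650 to 95.6 ± 23.6 TPM (-3.28 ± 0.42, adjusted p = 0.0137), NKAP, a regulator of NF-kappaB and of transcription (-2.88 ± 0.28, adjusted p = 0.00685), the receptor tyrosine kinase TIE1 (-2.59 ± 0.27, adjusted p = 0.00817) and the stromelysin MMP10 (-2.41 ± 0.44, adjusted p = 0.0371). Of 12492 genes tested, 192 rose and 240 fell, 47 and 103 of them at least 2-fold, and with the replicate block 3332 rose and 2399 fell. The libraries numbered 1 stood apart in both arms, and without them 1032 rose and 1008 fell, with 418 of the calls kept. Leaving out any single library not numbered 1 instead lowered both counts strongly, as given in the section on processing. 4 of 16 lists passed camera, 5 with the block and 0 with an estimated correlation (limma camera, lowest adjusted p = 0.201, with 2 at an unadjusted p under 0.05).

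**Figure D2:**
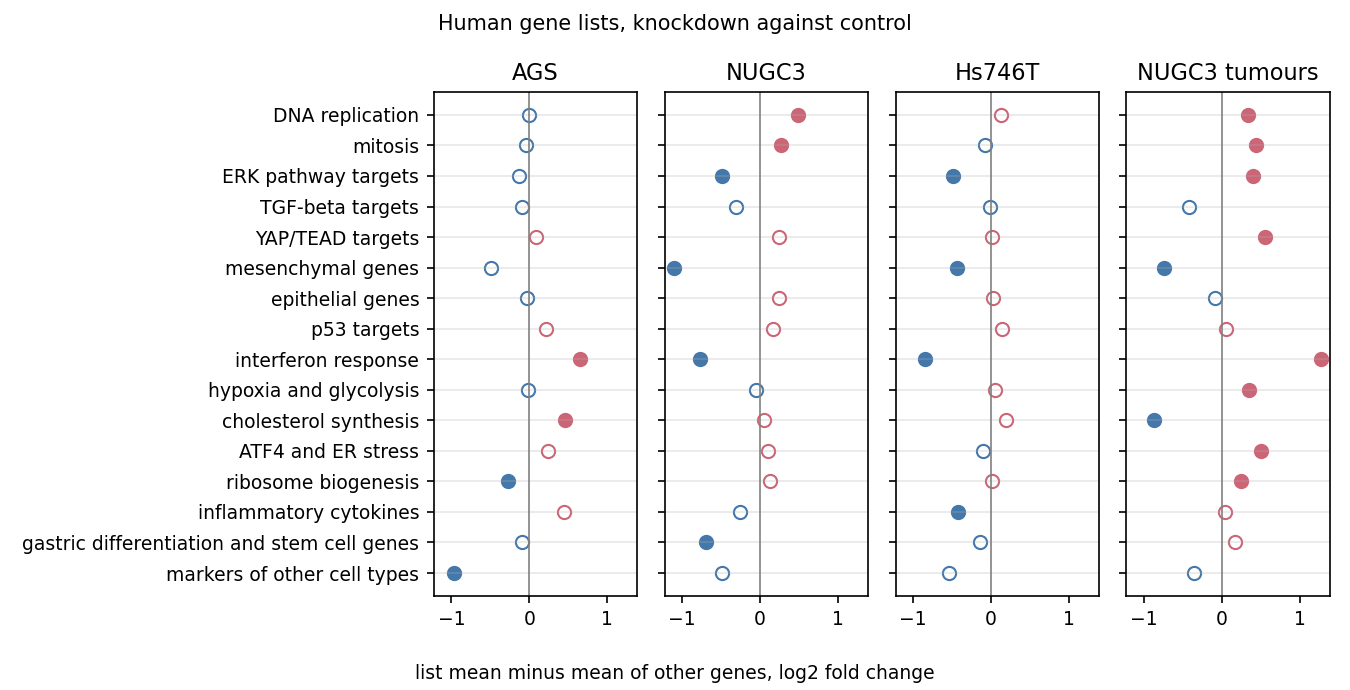
Mean log2 fold change of each of the 16 human gene lists minus the mean of other genes, for the 3 cultured lines and the human genes of NUGC3 tumours, with 1 point per list. Filled points passed camera at an adjusted p under 0.05 with a preset correlation, which no list did with an estimated correlation, and the interferon list lies at 0.65 in AGS, -0.77 in NUGC3 and -0.85 in Hs746T.

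Genes that changed in the same direction in all 3 lines numbered 123 higher and 91 lower of 10278 tested in each, against 7.32 and 6.25 expected of independent lists. With the replicate block they numbered 891 and 607, against 207 and 118 expected. Without a filter on expression fewer genes were shared in each direction, as given in the section on processing. MMP1 fell by 2.33 in AGS, 4.59 in NUGC3 and 3.28 in Hs746T on the log2 scale, and VIM by 1.24, 2.54 and 3.12. TSPAN13, a tetraspanin membrane protein, fell by 2.51, 2.79 and 2.31, and ACSL5, which activates long-chain fatty acids, by 2.35, 2.29 and 2.19. SRD5A1, a steroid 5-alpha-reductase, fell by 1.91, 2.70 and 1.86, while CAMK2N1, an inhibitor of CaM kinase II, fell by 1.13, 3.47 and 1.42, and SERPIND1, heparin cofactor II, by 1.04, 2.78 and 1.77. CCNG1 rose by 2.20, 2.16 and 2.00, and HEG1 by 1.98, 2.63 and 1.75. IQGAP3 completed the 10 genes with the largest mean change. Across genes, which are not independent replicates, the log2 changes of AGS and NUGC3 had a Pearson r of 0.49 over 10694 genes, AGS and Hs746T 0.458 over 10584, and NUGC3 and Hs746T 0.544 over 11129.

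Short sequence words in 3' UTRs, the untranslated ends of mRNAs where siRNAs and microRNAs bind through short seed matches, came with shifts in the changes of genes. Of 16384 words of 7 bases, 5 were past a Bonferroni threshold with one sign in all 3 lines, with UTR length and GC content as covariates. Genes with GTAAACC changed by 0.21 ± 0.02 (SE) more than other genes in AGS, 0.34 ± 0.02 in NUGC3 and 0.23 ± 0.01 in Hs746T, and by -0.02 ± 0.02 in the human genes of tumours. Genes with the overlapping word TAAACCA also lay higher in the 3 lines. Genes with GCCAAAT lay lower, by -0.14 ± 0.01 in AGS, -0.15 ± 0.02 in NUGC3 and -0.08 ± 0.01 in Hs746T, against -0.02 ± 0.02 in tumours, as did those with the overlapping words GAGTGGT and AGTGGTA. Genes with a word moved both ways. Of genes with GCCAAAT, 285 rose and 280 fell in AGS, 156 and 534 in NUGC3 and 15 and 33 in Hs746T. Of those with GTAAACC, 360 rose and 73 fell in AGS, 294 and 123 in NUGC3 and 95 and 4 in Hs746T. Risers made up 48.6%, 37.4% and 11.7% of the genes with GTAAACC, against 21.9%, 15.6% and 0.848% of genes without it. Of the genes higher in all 3 lines with a 3' UTR to search, 94 of 122 (77.0%) held GTAAACC or TAAACCA, against 17.4% of all 10053 genes searched, without a test because the words were picked on the changes of these same genes. CCNG1, HEG1, POLDIP2, SIRT2 and TMEM250 held GTAAACC, but so did AKR1C1, which fell in NUGC3, and POLDIP2 and AKR1C1 also held a word of falling genes. The 3' UTR searched for AKR1C1, the longest annotated, had 5541 bases, and whether the cells made that form is unknown. Of the genes lower in all 3 lines, 43 of 90 (47.8%) held one of the words of falling genes, against 24.4% of all. Read backwards, a comparison made after the result was seen, the words of rising genes were in 36.1% of the shared rising genes and 23.3% of all, and those of falling genes in 24.4% of the shared falling genes and 26.2% of all. CAMK2N1 and SERPIND1 held words of falling genes, while MMP1, TSPAN13, VIM, ACSL5, SRD5A1 and IQGAP3 held none. Other named genes held words too. SNAI2 held GCCAAAT, and so did CYP51A1, which rose in AGS. DUSP5, NKAP and MBP held GAGTGGT. ASNS, TPX2, MVD and CCL4L2 held TAAACCA, and IQGAP2, not called in AGS, held GTAAACC. Among the genes without these words, 28 rose and 47 fell in all 3 lines, against 2.11 and 3.50 expected of independent lists.

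**Figure D3:**
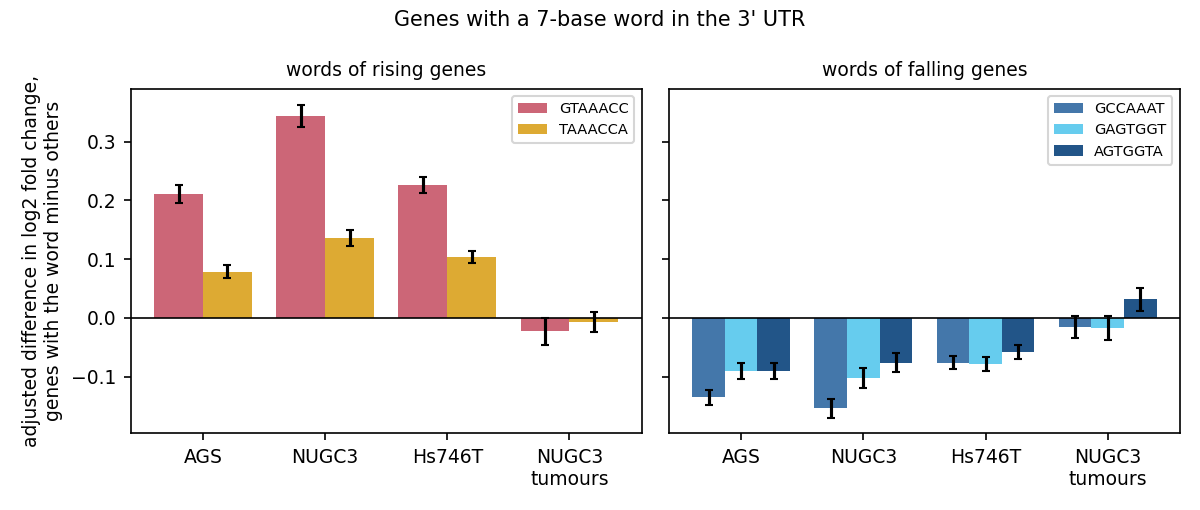
Difference in log2 fold change between genes with a 7-base word in the 3' UTR and other genes, with UTR length and GC content as covariates, for the 3 cultured lines and the human genes of NUGC3 tumours. Bars give the estimate and its SE across genes; GTAAACC lies at 0.21, 0.34 and 0.23 in the lines and at -0.02 in the tumours.

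The lines also differed from each other. The interferon response list lay 1.498 higher in AGS than in NUGC3 and 1.42 higher in AGS than in Hs746T, by the test of the difference itself over 21 genes (camera adjusted p = 2.95e-06 and 3.72e-11, and adjusted p = 0.598 and 0.268 with an estimated correlation). DNA replication genes lay higher in NUGC3 than in AGS by 0.34 and than in Hs746T by 0.22 (adjusted p = 3.99e-10 and 1.13e-05, and adjusted p = 0.31 and 0.615 with an estimated correlation). Single genes differed in number as well: 1563 between AGS and NUGC3, 670 between AGS and Hs746T and 1396 between NUGC3 and Hs746T, or 4360, 3086 and 4505 with the replicate block.

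Among the human genes of tumours labelled shIQGAP3, whose IQGAP3 was not called lower, mRNA was far higher from the chemokine genes CCL3, CCL4 and CCL5 and from antiviral genes. It was lower from cholesterol synthesis genes. CCL5, a chemokine for T cells and monocytes, rose from 40.5 ± 17.5 to 2232 ± 461 TPM (log2 change 5.81 ± 0.29, adjusted p = 2.43e-05). IFNL1, a type III interferon, rose from 0.08 to 63.3 ± 19.9 TPM (5.85 ± 0.24, adjusted p = 1.11e-05), and CCL3, another chemokine, from 0.09 ± 0.156 to 109 ± 12.8 TPM (6.66 ± 0.19, adjusted p = 4.82e-06). CCL4 (6.64 ± 0.22, adjusted p = 4.97e-06) and CCL4L1 (7.40 ± 0.24, adjusted p = 4.97e-06) rose too, though reads of such near-identical copies are uncertain. Of 25 interferon response genes, 11 rose, 0 fell and 14 were not called, or 11 higher and 1 lower adjusted over the list alone. OASL rose from 10.1 ± 3.16 to 312 ± 33.5 TPM (4.85 ± 0.23, adjusted p = 2.2e-05), and RSAD2, or viperin, by 4.59 ± 0.31 (adjusted p = 9.73e-05). The viral RNA sensors DDX58 and IFIH1 rose by 2.12 and 1.13 (adjusted p = 0.00137 and 0.0209). STAT2 (-0.54, adjusted p = 0.0964) and IRF9 (-0.30, adjusted p = 0.324), which carry the signal of interferon receptors, were not called. The list passed camera (adjusted p = 3.43e-08), with an adjusted p = 0.535 with an estimated correlation; its mean lay 1.27 above other genes and its median change was 0.17.

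Other chemokine genes of these tumours fell. Of 20 inflammatory cytokine genes, 2 rose, 5 fell and 13 were not called, or 6 higher and 6 lower adjusted over the list alone. CCL20, which attracts dendritic cells and lymphocytes, fell from 1734 ± 593 to 98.9 ± 8.53 TPM (log2 change -4.06 ± 0.26, adjusted p = 8.08e-05), and the neutrophil chemokines CXCL3, CXCL8, CXCL1 and CXCL2 fell by 1.95, 1.89, 1.18 and 1.05 (adjusted p = 0.00443, 0.00642, 0.0132 and 0.0282). IL6, an inflammatory cytokine, rose by 3.87 ± 0.26 (adjusted p = 8.88e-05). The list did not pass camera (adjusted p = 0.223, and adjusted p = 0.705 with an estimated correlation), and its mean change of -0.13 differed in sign from its median of 0.24 and from the test, which placed it above other genes.

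Cholesterol synthesis genes fell in these tumours, 14 of 20, with 0 higher and 6 not called, or 19 lower adjusted over the list alone. SREBF2, the transcription factor that switches on the pathway, fell from 119 ± 5.11 to 48.8 ± 11.7 TPM (log2 change -1.30 ± 0.19, adjusted p = 0.00345). Camera gave an adjusted p = 2.56e-10, and an adjusted p = 0.466 with an estimated correlation. Mesenchymal genes lay lower, with 4 of 10 falling, 1 rising and 5 not called, also when adjusted over the list alone (camera adjusted p = 0.0242, and adjusted p = 0.535 with an estimated correlation). The matrix protein tenascin C, TNC, fell by 4.04 (adjusted p = 0.000319), the integrin ITGA5 rose by 1.03 (adjusted p = 0.0197), and VIM was at 152 and 141 TPM (-0.11, adjusted p = 0.772). Without shCtrl replicate 2 or 3 the mesenchymal list had an adjusted p of 0.0641 and 0.105.

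Several lists lay above other genes in these tumours with few members called, and each had more called without shIQGAP3 replicate 2. For ATF4 and ER stress genes, 4 of 21 rose, 0 fell and 17 were not called, or 6 higher and 2 lower adjusted over the list alone. The stress factor ATF3 rose by 1.49 ± 0.17 (adjusted p = 0.0011) and CHAC1, which breaks down glutathione, by 1.14 ± 0.22 (adjusted p = 0.0137), and camera gave an adjusted p = 4.89e-05 and an adjusted p = 0.192 with an estimated correlation. Of 22 ERK targets, 4 rose, 1 fell and 17 were not called, also when adjusted over the list alone, with the ERK phosphatases DUSP4 and DUSP5 up by 1.25 ± 0.23 and 1.08 ± 0.20 (adjusted p = 0.0131 and 0.0133). Of 16 YAP/TEAD targets, 3 rose, 0 fell and 13 were not called, or 5 higher adjusted over the list alone, led by ANKRD1 (2.59, adjusted p = 0.000158). Both lists had a camera adjusted p = 0.00076, and an adjusted p = 0.535 with an estimated correlation. Mitosis (1 of 30 higher, 0 lower, 29 not called; 0 adjusted over the list alone) and DNA replication genes (1 of 31 higher, 0 lower, 30 not called, also over the list alone) had adjusted p = 1.06e-05 and 0.000176, and both an adjusted p = 0.535 with an estimated correlation. Their called members were UBE2C, of the anaphase-promoting pathway (0.70 ± 0.16, adjusted p = 0.0308), and CCNE1, cyclin E1 (0.88 ± 0.15, adjusted p = 0.00759). UBE2C lost its call without any of 5 libraries (limma adjusted p = 0.0674 to 0.0997), and CCNE1 without any of 2 (0.0612 and 0.067). Hypoxia and glycolysis (1 of 20 higher, 1 lower, 18 not called; 5 and 2 adjusted over the list alone) and ribosome biogenesis (1 of 20 higher, 0 lower, 19 not called, also over the list alone) had adjusted p = 0.00225 and 0.0105, and both an adjusted p = 0.535 with an estimated correlation. Hypoxia and glycolysis had an adjusted p of 0.141 without shCtrl replicate 1, as did ribosome biogenesis without shCtrl replicate 2. Without shIQGAP3 replicate 2, 11 YAP/TEAD targets rose and 1 fell, 11 mitosis genes rose and 0 fell, and 9 ERK targets rose and 2 fell. The same setting gave 7 higher and 2 lower for both ATF4 and ER stress and hypoxia and glycolysis, 6 and 0 for DNA replication and 2 and 0 for ribosome biogenesis.

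The largest falls in the human genes of tumours were in OLFM4, a glycoprotein of gastrointestinal stem cells, from 2896 ± 447 to 32.0 ± 14.5 TPM (log2 change -6.56 ± 0.33, adjusted p = 2.74e-05), and PLA2G2A, a secreted phospholipase, from 99.9 ± 2.68 to 0.427 ± 0.293 TPM (-6.16 ± 0.20, adjusted p = 4.82e-06). The keratins KRT1 (-6.05 ± 0.27, adjusted p = 1.63e-05) and KRT4 (from 74.5 ± 14.6 to 0.167 ± 0.119 TPM, adjusted p = 4.97e-06) and the metalloproteinase MMP7 (-5.94 ± 0.19, adjusted p = 4.82e-06) fell by similar amounts. Of 12308 genes tested, 359 rose and 866 fell, 233 and 576 of them at least 2-fold. The library medians differed by -0.18 on the log2 scale, and with that shift removed 560 rose and 769 fell, or 646 and 792 after quantile normalisation. Library shIQGAP3 replicate 2 stood apart, with a median of 7.83 TPM against 11.7 in both other shIQGAP3 libraries, and without it 908 rose and 1590 fell, with 1138 of the calls kept. Leaving out any other single library lowered the number that rose, as given in the section on processing. 10 of 16 lists passed camera and 0 with an estimated correlation (limma camera, lowest adjusted p = 0.192, with 1 at an unadjusted p under 0.05).

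Among the mouse genes, tumours labelled shIQGAP3 held more mRNA from interferon-stimulated genes and less from genes of proliferation, matrix remodelling, pericytes, smooth muscle and endothelium. Of 18 interferon response genes, 14 rose, 0 fell and 4 were not called, and all 18 rose adjusted over the list alone. Irf7, the factor that amplifies the interferon response, rose from 374 ± 58.2 to 2972 ± 679 TPM (log2 change 2.97 ± 0.21, adjusted p = 0.000475), and Oas3, which senses double-stranded RNA, from 10.7 ± 1.93 to 102 ± 53.9 TPM (2.96 ± 0.46, adjusted p = 0.00716). Stat2, which carries the signal of interferon receptors, rose by 1.97 (adjusted p = 0.0133). Camera gave an adjusted p = 3.94e-21, and an adjusted p = 0.175 with an estimated correlation. All 18 proliferation genes fell, also when adjusted over the list alone, such as Top2a, a topoisomerase of dividing cells, from 61.9 ± 18.2 to 9.18 ± 4.23 TPM (-2.69 ± 0.40, adjusted p = 0.00612), and cyclin A2, Ccna2 (-2.62 ± 0.31, adjusted p = 0.00259). The proliferation list had an adjusted p = 5.98e-12, and an adjusted p = 0.21 with an estimated correlation.

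Matrix and vessel genes fell in the mouse compartment. Of 17 matrix remodelling genes, 10 fell, 0 rose and 7 were not called, or 15 lower adjusted over the list alone. The collagenase Mmp13 fell from 4335 ± 944 to 286 ± 132 TPM (log2 change -4.00 ± 0.34, adjusted p = 0.000796) and the protease Adam12 by 2.62 ± 0.49 (adjusted p = 0.0136), and camera gave an adjusted p = 3.52e-07 and an adjusted p = 0.21 with an estimated correlation. Of 14 endothelial genes, 8 fell, 0 rose and 6 were not called, or 9 lower adjusted over the list alone. Cdh5, the cadherin of endothelial junctions, fell by 2.04 ± 0.41 (adjusted p = 0.0183) and Emcn by 1.99 ± 0.19 (adjusted p = 0.00138), and the list had an adjusted p = 0.000212, and an adjusted p = 0.355 with an estimated correlation. Of 10 pericyte genes, 5 fell, 0 rose and 5 were not called, or 8 lower adjusted over the list alone, including Rgs5 (-2.44 ± 0.53, adjusted p = 0.0235) and Mcam (-1.88 ± 0.20, adjusted p = 0.00158). Camera gave them an adjusted p = 0.000336, and an adjusted p = 0.21 with an estimated correlation. Of 10 smooth muscle and myofibroblast genes, 5 fell, 0 rose and 5 were not called, or 6 lower adjusted over the list alone, with Actg2, enteric smooth muscle actin, from 391 ± 147 to 11.1 ± 2.24 TPM (-4.97 ± 0.28, adjusted p = 0.000174) and Acta2, alpha smooth muscle actin, down by 3.09 (adjusted p = 0.000897). That list had an adjusted p = 0.00526, and an adjusted p = 0.417 with an estimated correlation.

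Fibroblast genes were mixed: 10 of 20 fell, 1 rose and 9 were not called, or 12 lower and 3 higher adjusted over the list alone. Fap, a protease of activated fibroblasts, fell by 2.21 (adjusted p = 0.000785), while the proteoglycan Dcn rose by 0.94 (adjusted p = 0.0404). Camera gave an adjusted p = 0.0166, an adjusted p = 0.501 with an estimated correlation, and an adjusted p of 0.085 without shIQGAP3 replicate 1. Of 18 TGF-beta targets, 8 fell, 0 rose and 10 were not called, or 10 lower adjusted over the list alone. The list had an adjusted p = 0.00169, and an adjusted p = 0.417 with an estimated correlation. Of 14 skeletal muscle genes, 1 rose, 0 fell and 13 were not called, or 6 higher adjusted over the list alone. The riser was Pvalb, a calcium buffer of fast muscle fibres, from 64.5 ± 101 to 875 ± 264 TPM (5.33 ± 1.16, adjusted p = 0.0245). Without shIQGAP3 replicate 2, 0 of the 14 were called. The list passed camera (adjusted p = 8.55e-08, and adjusted p = 0.355 with an estimated correlation), but its level differed widely between control libraries, with a median deviation from the group of 3.73 in shCtrl replicate 1 and -3.79 in shCtrl replicate 2, on the log2 scale. Of 10 adipocyte genes, 1 rose, 0 fell and 9 were not called, also when adjusted over the list alone, Pparg being the one that rose (2.28, adjusted p = 0.0276); camera gave an adjusted p = 0.00378, an adjusted p = 0.417 with an estimated correlation, and an adjusted p of 0.148 without shIQGAP3 replicate 1.

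Of 10 mouse dendritic cell genes, 2 rose, 1 fell and 7 were not called, or 3 and 1 adjusted over the list alone. Clec9a and Batf3, of cross-presenting dendritic cells, rose by 1.81 and 1.92 (adjusted p = 0.0242 and 0.0413) and the integrin Itgax fell by 1.10 (adjusted p = 0.0281); camera gave an adjusted p = 0.0166 and an adjusted p = 0.355 with an estimated correlation. Of 16 macrophage and monocyte genes, 2 rose, 0 fell and 14 were not called, also when adjusted over the list alone, among them the antibody receptor Fcgr1 (1.79, adjusted p = 0.000755). Of 18 inflammatory cytokine genes, 3 rose, 1 fell and 14 were not called, or 4 and 1 adjusted over the list alone, with Tnf up by 1.82 (adjusted p = 0.0262) and Il1b down by 1.03 (adjusted p = 0.0321). Both lists had a camera adjusted p = 0.0259 above other genes and an adjusted p = 0.417 with an estimated correlation, though the macrophage median change was -0.02. Of 3 lymphocyte and NK cell genes, 0 were called, or 1 higher adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.355 with an estimated correlation). Of 9 neutrophil genes, 2 fell, 0 rose and 7 were not called, or 5 lower adjusted over the list alone, led by Mmp9, a gelatinase (-2.02, adjusted p = 0.00264); the list had an adjusted p = 0.0337, and an adjusted p = 0.355 with an estimated correlation. Without shIQGAP3 replicate 2, 5 macrophage and 2 lymphocyte genes rose and 4 neutrophil genes fell. Of these 5 lists, dendritic cells lost the call without shIQGAP3 replicate 2 (adjusted p = 0.0927), macrophages without shCtrl replicate 1 or 3 (0.0861 and 0.0898), cytokines without shCtrl replicate 1 (0.17), lymphocytes without shIQGAP3 replicate 1 or 3 (0.0684 and 0.0517) and neutrophils without shCtrl replicate 2 or shIQGAP3 replicate 1 or 3 (0.097, 0.0628 and 0.0815). Hypoxia and glycolysis (0 of 15 higher, 2 lower, 13 not called, adjusted p = 0.135), nerve and Schwann cell (0 of 5 higher, 1 lower, 4 not called, adjusted p = 0.323) and red blood cell genes (0 of 5 higher, 1 lower, 4 not called, adjusted p = 0.392) did not pass camera.

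**Figure D4:**
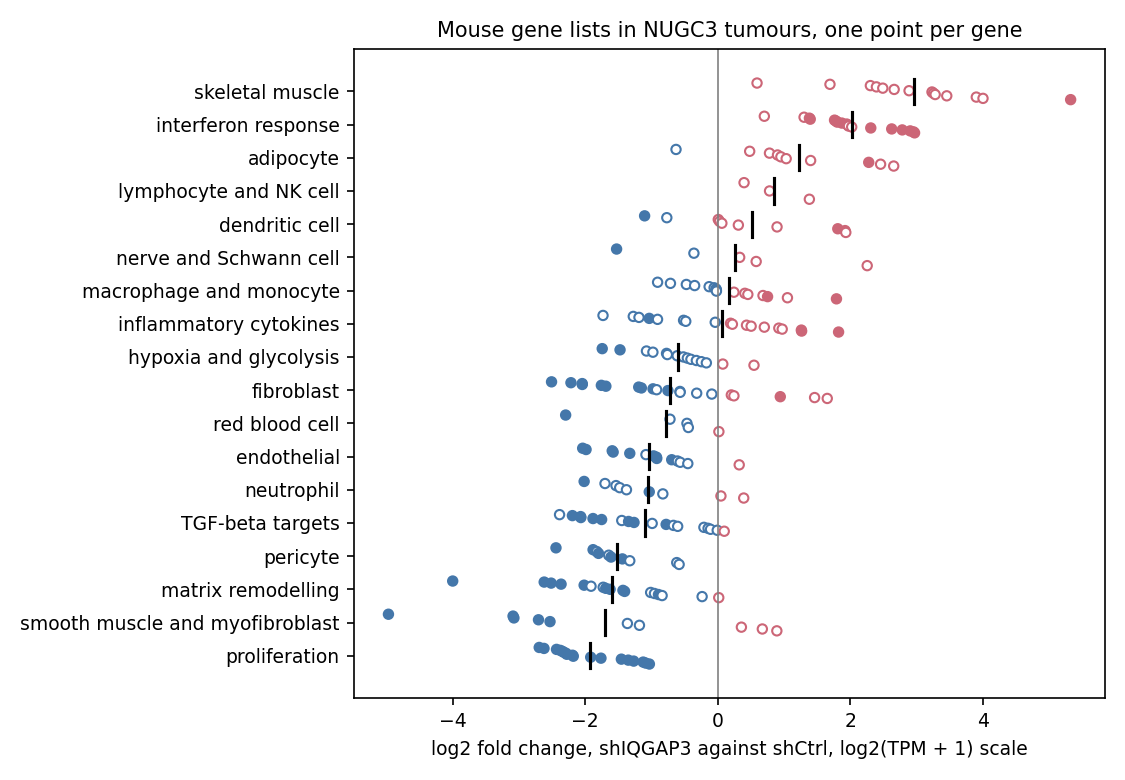
Log2 fold change, on the log2(TPM + 1) scale, of each mouse gene of the 18 lists tested in NUGC3 tumours, shIQGAP3 against shCtrl, with 1 point per gene and a black line at each list's mean. Filled points are genes called at an adjusted p under 0.05: 14 of 18 interferon response genes rose and all 18 proliferation genes fell.

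The largest rises in the mouse genes, beside Pvalb, were in the predicted gene Gm15056, from 1.06 ± 1.84 to 197 ± 50.8 TPM (log2 change 6.91 ± 0.57, adjusted p = 0.000735), Ly6i (5.69 ± 0.86, adjusted p = 0.00655), which has close relatives and is uncertain, the kallikrein Klk1 (4.97 ± 0.48, adjusted p = 0.00137) and Cxcl9, a chemokine induced by interferon gamma, from 13.5 ± 2.95 to 368 ± 138 TPM (adjusted p = 0.000475). The largest falls, beside Actg2 and Mmp13, were in Stra6, the retinol transporter (-5.36 ± 0.59, adjusted p = 0.002), B3galt5 (-4.33 ± 0.32, adjusted p = 0.000475) and the basophil protease Mcpt8 (-3.86 ± 0.47, adjusted p = 0.00293). Of 10885 genes tested, 445 rose and 998 fell, 380 and 775 of them at least 2-fold. The library medians differed by -0.311 on the log2 scale, and with that shift removed 701 rose and 570 fell, or 747 and 916 after quantile normalisation. Without shIQGAP3 replicate 2, whose median was 5.57 TPM against 10.2 and 9.79 in the other shIQGAP3 libraries, 802 rose and 1435 fell, with 1360 of the calls kept. Leaving out any other single library lowered the number that fell, as given in the section on processing. 15 of 18 lists passed camera and 0 with an estimated correlation (limma camera, lowest adjusted p = 0.175, with 4 at an unadjusted p under 0.05).

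The siRNA effect in cultured NUGC3 cells and the shRNA effect in NUGC3 tumours were weakly correlated. Among 11702 human genes tested in both, 52 rose in both (46.5 expected of independent lists), 264 fell in both (167 expected) and 192 went opposite ways (179 expected). The number that rose in both was 112 with median centring and 139 after quantile normalisation, but these settings also called more genes higher in each comparison. In cultured NUGC3 2996 and 2931 rose with them, against 2057, and in tumours 560 and 646, against 359. The 46.5 expected holds only for the values as they stood and cannot be set beside the 112 and 139. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.102 and a Spearman rho of 0.139. OLFM4 fell in both, by 1.07 in culture and 6.56 in tumours, and so did AKR1C3, by 3.35 and 3.69. Interferon response genes lay lower in cultured NUGC3 and higher in tumours, and this difference was not tested. Human IQGAP3 was not called lower in these tumours, which bears on any direction read from this comparison.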

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

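The tests of reads shared between species, of tumour library shIQGAP3 replicate 2 as the source of the interferon signal and of cultured NUGC3 cells against tumours were chosen after the result was seen, as was the comparison of genes with and without a word.

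The effect of siIQGAP3 differed between cell lines by the test of the difference itself. AGS differed from NUGC3, as a difference of mean log2 changes, by 1.498 for interferon response genes, 0.72 for inflammatory cytokines (adjusted p = 0.0441), 0.551 for cholesterol synthesis (adjusted p = 0.00444), -0.343 for DNA replication, -0.259 for ribosome biogenesis (adjusted p = 0.000275) and -0.167 for mitosis (adjusted p = 0.0015). From Hs746T, AGS differed by 1.42 for interferon response, 0.832 for cytokines (adjusted p = 9.36e-05), 0.586 for mesenchymal genes (adjusted p = 0.0293), 0.432 for ATF4 and ER stress (adjusted p = 0.000543), 0.289 for ERK targets (adjusted p = 0.00473), 0.281 for cholesterol synthesis (adjusted p = 0.0177) and -0.273 for ribosome biogenesis (adjusted p = 0.0037). NUGC3 differed from Hs746T by 0.219 for DNA replication and 0.208 for mitosis (adjusted p = 1e-04). With an estimated correlation in camera the lowest adjusted p among these was 0.175.

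Among the genes that changed alike in all 3 lines, several differed in size. MMP1 fell less in AGS than in NUGC3 (difference 2.259), VIM fell less in AGS than in NUGC3 (1.298) and Hs746T (1.878), and SERPIND1 fell less in AGS than in NUGC3 (1.736). VIM started at 3.87 TPM in AGS, 7.09 in NUGC3 and 5939 in Hs746T. SERPIND1 started at 1.22 TPM in AGS, where it fell to 0.08, and at 6.83 in NUGC3. As log2(TPM + 1) leaves low genes little room to fall, the differences for VIM and SERPIND1 do not show a weaker effect in AGS. SRD5A1 and CAMK2N1 fell most in NUGC3, with differences of 0.788 and 2.343 for AGS minus NUGC3 and of -0.836 and -2.046 for NUGC3 minus Hs746T.

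The first pattern weighed is that 123 genes rose and 91 fell in all 3 siRNA-treated lines. Seed matches of the siRNA pools are a candidate explanation: 5 words of 7 bases passed the Bonferroni threshold with one sign in all 3 lines and none of them in the tumours, which had another construct (t for GTAAACC of 14.0, 18.6 and 17.4 in AGS, NUGC3 and Hs746T and -0.483 in tumours). A word of rising genes may reflect targets of the control pool, lower in siCtrl, rather than genes that IQGAP3 holds down, but the siRNA sequences are not given in the sources used here, so the words were not matched to them. Loss of IQGAP3 as the shared cause cannot be told apart by the tumours: 39.2% of shared genes had the same sign there, against 67.5% of genes called in NUGC3 cells alone (Fisher's exact test, two-sided, p = 9.91e-16). By direction this was 21.1% against 48.6% of genes that rose (p = 7.73e-09) and 64.0% against 77.6% of genes that fell (p = 0.00605, both by the same exact test). Genes are not independent replicates, so these p-values do not measure the spread between samples. Nor were the shares adjusted for UTR length or GC content. In tumours genes with GTAAACC changed by -0.257 on average and other genes by -0.164, but the adjusted difference was -0.02 ± 0.02. The 39.2% meets the bound set beforehand for a result against loss of IQGAP3. That bound assumed that the tumours had lost IQGAP3, which the values do not show. Human IQGAP3 stood at 77.3% of control (log2 change -0.37 ± 0.21, limma adjusted p = 0.396). This lay well above the change of -2.01 ± 0.49 in cultured NUGC3 cells, which argues against a loss of that depth in the mRNA. A smaller loss is neither shown nor excluded. On simulated data this comparison recovered only 5.97% of 1.5-fold and 34.3% of 2-fold changes, shares over many genes rather than for IQGAP3 itself. Without a word of rising genes 28 genes rose in all 3 lines, and without a word of falling genes 47 fell. Independent lists would give 2.11 and 3.50. These counts cannot decide whether a seed effect covers only part of the pattern. Only words past the threshold in all 3 lines were counted, and any cause shared by the lines would exceed independent lists. Loss of IQGAP3 therefore stays open.

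The second pattern is the rise of interferon response genes, and of single CCL chemokine genes, in tumours labelled shIQGAP3, where no list of chemokines was tested and the human cytokine list did not pass camera (limma adjusted p = 0.223). Without shIQGAP3 replicate 2 the mouse interferon list kept a mean log2 change of 2.25, but this could not decide, as its level there was the lowest of its arm. One bad library as the source is argued against by the mean levels of the list, on the log2(TPM + 1) scale. They were 7.23, 6.63 and 7.39 in the shIQGAP3 libraries and 5.13, 4.98 and 5.05 in the shCtrl libraries. An effect of lower IQGAP3 common to NUGC3 cells in culture and in tumours would have raised the human list in culture too. There, 17 of 21 genes of the human list fell. That list lay at -0.77 relative to other genes (limma camera adjusted p = 4.14e-05, but adjusted p = 0.421 with an estimated correlation). These values meet the bound set against such a common effect, but they cannot decide. Human IQGAP3 was not called lower in the tumours, where it stood at 77.3% of control. The changes in culture may also hold effects of the siRNA pools themselves. Human reads counted on mouse genes are argued against for the 9 mouse members whose human namesakes were not called, which exceeded these by a median log2 change of 2.26, each by at least 3.24 joint standard errors, and rose by at least 0.756 TPM per human TPM where the highest mouse level of an epithelial gene was 0.0791 per human TPM. For the 9 whose namesakes rose such reads cannot be told apart from a host response: over all 18 members the median excess was 0.97 (11 above 0, exact sign-flip permutation test, two-sided, p = 0.0991), and 16 rose by more than 0.0791 TPM per human TPM, but this ratio comes from other genes and may differ by sequence. Mouse reads counted on human genes, the stable shRNA itself, a clonal difference between the cell stocks and a response of the host to the tumour stay open and were not tested.

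The third pattern is that tumour library shIQGAP3 replicate 2 stood apart in both species' tables. Degraded RNA is consistent with its Spearman correlation, across human genes alone as no mouse lengths were at hand, of -0.573 between its deviation from the other shIQGAP3 libraries and transcript length, below those of the other 5 libraries (-0.277 to 0.535). Skeletal muscle in the piece taken is argued against by a median deviation of -0.88 for the mouse muscle genes, where values reached 3.73 in shCtrl replicate 1. No other explanation was tested, and a difference in library preparation stays open.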

How the results depend on the processing

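Leaving out both libraries numbered 1 of Hs746T and mirroring the table filter were chosen after the data had been seen. None of the gene, list or correlation results reversed, though the excess of falls over rises did so with median centring in NUGC3 (2996 higher and 2581 lower) and in the mouse genes. In all, 1714 gene, 1092 list and 7 correlation results under an alternative kept their side of the threshold, while 113, 35 and 0 lost it and 10, 35 and 0 gained it. The joint fit called 1446 genes higher and 966 lower in AGS and 1258 and 735 in Hs746T, which share their variance with the other lines there. An estimated correlation left 0 lists past the threshold in AGS, 0 in NUGC3, 0 in Hs746T and 0 in both tumour tables (limma camera). Without a filter Hs746T had 93 and 121, the lines shared 60 and 48 and AGS and Hs746T differed in 1032 genes. The replicate block gave 3332 and 2399 in Hs746T, 891 and 607 shared genes, and 4360 (AGS against NUGC3), 3086 (AGS against Hs746T) and 4505 (NUGC3 against Hs746T) genes that differed, as it removes a difference common to equally numbered libraries. It changed no call of a named gene or list in the lines beyond those given with the results. In the tumours the numbers did not pair (correlations from -0.38 to 0.5 in the human and -0.0385 to 0.228 in the mouse genes), and the block there changed the call of 1 list, the human TGF-beta targets (6 of 23 lower, adjusted p = 0.0505, or 0.0434 with the block and 0.595 with the block and an estimated correlation). Without both libraries numbered 1 Hs746T had 1032 and 1008. In the human genes of tumours the 5 TPM filter gave 216 and 519 (28 higher and 134 lower also in cultured NUGC3), median centring 560 higher (112 in both) and quantile normalisation 646 higher (139 in both). In the mouse genes median centring gave 701 and 570 and quantile normalisation 747 higher. Where no cause is named, the cause was not tested.

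Settings other than leaving out 1 library or an estimated correlation ended these calls, with the adjusted p in parentheses. Without a filter the markers of other cell types in AGS (0.347), the gastric genes of NUGC3 (0.215) and the mesenchymal genes of tumours (0.504) lost theirs. With the 5 TPM filter it was the mesenchymal (0.058) and gastric genes (0.221) of NUGC3, the mesenchymal genes of tumours (0.0712) and the mouse dendritic cell (0.16) and cytokine genes (0.0589). The gastric list also lost it with a pseudocount of 0.1 (0.0505), and the mouse neutrophil list without trend (0.0642). After quantile normalisation hypoxia and glycolysis (0.139) and ribosome biogenesis (0.0965) of the human tumour genes and the mouse macrophage (0.232), dendritic cell (0.195) and cytokine genes (0.0775) lost it, and with median centring the mouse macrophage (0.05) and cytokine genes (0.0949). Of called genes in Hs746T, MMP10 (0.073), ISG20 (0.084), IL1A (0.0815), MMP14 (0.0649) and SERPIND1 (0.084) lost their call without a filter, and ISG20, IL1A, MMP14 and SERPIND1 in other settings too. Lists gained a call in AGS with quantile normalisation (ATF4 and ER stress, 0.0448), in Hs746T without a filter (DNA replication, 0.0357), with the 5 TPM filter (markers of other cell types, 0.0329) and without both libraries numbered 1 (both lists, 0.00381 and 0.021), and in the human tumour genes (TGF-beta targets, 0.00471 to 0.049 in 6 settings). Among genes, RRM2 gained one in Hs746T with the 5 TPM filter (0.0458) and quantile normalisation (0.0439), and MBP and RRM2 without both libraries numbered 1 (0.006 and 0.00293).

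Leaving out 1 library moved the counts of Hs746T and the tumours. Hs746T ranged from 6 to 248 higher and 12 to 267 lower, with 28 and 26 without siCtrl replicate 2, 9 and 15 without siCtrl replicate 3, 115 higher without siIQGAP3 replicate 1, 15 and 20 without siIQGAP3 replicate 2 and 6 and 12 without siIQGAP3 replicate 3. The human genes of tumours ranged from 157 to 908 higher and 274 to 1590 lower, with 179 and 274 without shCtrl replicate 1, 197 and 281 without shCtrl replicate 2, 202 and 346 without shCtrl replicate 3, 200 higher without shIQGAP3 replicate 1, 908 and 1590 without shIQGAP3 replicate 2 and 157 higher without shIQGAP3 replicate 3. The mouse genes ranged from 210 to 802 higher and 317 to 1435 lower, with 334 lower without shCtrl replicate 1, 275 and 385 without shCtrl replicate 2, 232 and 317 without shCtrl replicate 3, 239 and 513 without shIQGAP3 replicate 1, 802 higher without shIQGAP3 replicate 2 and 210 and 497 without shIQGAP3 replicate 3. AGS stayed at 2072 to 2767 higher and 1448 to 1856 lower, and NUGC3 at 1406 to 2064 and 2413 to 3833.

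Of the named genes called, leaving out 1 library ended the call of 4 of 32 in AGS (NPPB, HEG1, CYP51A1 and MVD, adjusted p up to 0.0921), 2 of 30 in NUGC3 (AKR1C1, up to 0.0602, and IQGAP3, up to 0.084), 13 of 22 in Hs746T (AREG, CCNG1, CXCL8, DUSP5, IL1A, ISG20, MMP1, MMP10, MMP14, NKAP, SERPIND1, SIRT2 and TIE1, up to 0.216), 6 of 21 in the human genes of tumours (among them CCNE1, CHAC1, DUSP4, DUSP5 and UBE2C, up to 0.0997) and 6 of 20 in the mouse genes (Adam12, Cdh5, Iqgap3, Ly6i, Pvalb and Rgs5, up to 0.14). TPM keeps no depth, so what depth limits could not be measured.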

Other observations

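The counts of genes called were set against every other split of the same 6 libraries into 3 and 3. In AGS 4656 genes were called in the real split and 0 in the highest other, in NUGC3 5349 and 0, in Hs746T 432 and 0, in the human genes of tumours 1225 and 0, and in the mouse genes 1443 and 0, each by limma. At an unadjusted p under 0.05 the real splits gave 5601, 6280, 2520, 2574 and 3132 genes and the highest other 278, 748, 2458, 1791 and 552. In each comparison 1 of the 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The other splits also mix the arms, so a difference between arms widens the spread within their groups and lowers their calls. Their 0 calls therefore do not measure how many genes would be called without a difference between arms. In the 3 cell lines, where the numbers pair the libraries, 4 splits part all 3 pairs, and the other such splits called 0 genes. In Hs746T the other splits that put both libraries numbered 1 in one group gave 925 to 2458 genes at an unadjusted p under 0.05, and those that parted them 8 to 55, which points to a structure by replicate number. In the human genes of tumours the 1791 came from the split that set shCtrl replicates 1 and 2 and shIQGAP3 replicate 2 against the rest.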
